A study of Homo sapiens with 6 samples.

How the data were processed

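RNA from MDA-MB-231 cells grown in DMEM with 10% fetal bovine serum was compared after 24 h with 1 µM loonamycin A or with DMSO, in 3 libraries per group. Per the labels' protocols, RNA was harvested with Trizol and libraries were made with the Illumina TruSeq RNA kit from 1 µg of total RNA. The extraction protocol speaks of retinas, which does not match the cell line of the other labels, so retina markers were among the lists examined. The loonamycin A libraries carry the undefined name C48, which the treatment labels tie to that compound.

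The values were used as deposited: per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to hg38 (GRCh38.p12), and the authors deposited FPKM (fragments per kilobase of gene length, scaled for library size). The counting tool, its strand setting and the annotation release were not given in the sources used here. Each deposited FPKM times the deposited gene length was a whole multiple of one step per library, within 0.0001 for 100% of values, which gave whole reads per gene. The 6 steps matched median-of-ratios size factors of 1.05777, 1.02938, 1.1085, 1.06746, 0.865491 and 0.930836 (DMSO 1 to 3, then loonamycin A 1 to 3), so the FPKM already carried such a scaling. The recovered reads ranged from 16687128 to 18671338 per library.

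The file held 59059 genes, of which 11317 had a mean FPKM of at least 1 over the 6 libraries and were tested. Of the tested genes, 341 were defined by the submitters' pipeline and had no annotated name, 215 lay on alternative contigs, and 16 had names changed into dates, which were restored from their identifiers. Span, coordinates, overlaps and biotype came from the file, and GC content, for 96.9% of tested genes, from the longest transcript of each gene in the GENCODE reference.

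Values were log2(FPKM + 1). Fold changes, standard errors (SE) and adjusted p came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior), with treatment as the only term, a two-sided test and Benjamini-Hochberg adjustment over all tested genes at 0.05. Fold changes in the text are differences of the group means on this log2 scale. Gene lists were tested with limma's camera at a preset correlation of 0.01, over the 37 of 41 lists with at least 5 tested members, and again with an estimated correlation and with fry. The text does not describe 1 of the tested lists, which the counts of lists include. Trends with span, exonic length and GC content were fitted as splines over the protein-coding genes outside a list and subtracted from its members. For the protein families the fit did not leave out the family's own members. The span comparison and the expression shares used exact two-sided permutation tests over the 20 assignments of 3 against 3 libraries, whose smallest p is 0.1. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

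The groups, tests, gene lists, the alternatives marked as planned and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest increases and 12 largest decreases among protein-coding genes that passed, had a mean FPKM of at least 5 in the higher group and did not overlap between groups. It also named up to 4 members of each list described, by smallest p, and 15 fixed genes. The text uses 2 members per list, a number set after the values were seen, and names further members of the 5 passing lists where it says so.

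The methods were tested on simulated reads over 10861 genes with a dispersion taken from these libraries. limma called 81 of 96 genes with a planted 2-fold change (84.4%) and 90 of 90 with a planted 4-fold change, and 21 of its 192 calls (10.9%) were on unchanged genes, above the nominal 5%. After that share was seen, limma voom on recovered reads was added, which called 90 of 96 and 90 of 90, with 9 of 189 calls (4.76%) on unchanged genes. limma's camera separated a shifted list from an unshifted one, and a planted span difference of -1.00 was recovered as -1.04. Both shifts were added directly to the log2 values of the treated libraries, so these 2 results check only the calculation. The simulated genes varied independently of each other and few were changed. The false shares and the camera result therefore need not carry over to the real libraries.

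Alternatives changed the pseudocount, the filter, the scaling, the prior, the test, the replicate term, the set of genes and the libraries included. Some were added after the data were seen: voom, the removal of trends with GC content and exonic length, the omission of or a term for DMSO 3 and loonamycin A 1, and chromosomes without alternative contigs. No library was left out of the values given as results.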

Results

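RNA sequencing was performed on MDA-MB-231 cells, a triple-negative human breast cancer line, after 24 h with 1 µM loonamycin A or with the solvent DMSO. Loonamycin A is an indolocarbazole alkaloid, a compound class that includes staurosporine and rebeccamycin. The design asked which transcripts differed between treated and untreated cells. Each group held 3 libraries, named here by group and replicate (DMSO 2 is DMSO replicate 2). The whole reads recovered from the deposited values came to 18671338, 17454149 and 16812003 for DMSO 1 to 3, and to 17243694, 16687128 and 17213199 for loonamycin A 1 to 3. Between 11014 and 11504 genes per library reached an FPKM of 1. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

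Loonamycin A lowered 19 of 32 tested genes of the list of integrated stress response genes and ATF4 targets, ATF4 among them, and genes that included VAV2 and EGFR, and raised genes that included CTGF, the histone variant H2AFJ and the cholesterol synthesis enzyme IDI1. The guanine nucleotide exchange factor VAV2 fell from an FPKM of 29.7 ± 2.42 to 3.65 ± 0.59 (SD, n = 3 per group), and the growth factor receptor EGFR from 12.5 ± 3.49 to 1.65 ± 0.0628. The stress transcription factor ATF4 fell from 158 ± 25.6 to 37.8 ± 3.88. CTGF, a secreted matricellular protein, rose from 2.22 ± 0.165 to 10.1 ± 1.59, and MARCKSL1, an actin-regulating membrane protein, from 23.6 ± 3.01 to 91.5 ± 11.2. Of 11317 genes tested with limma, 3472 (30.7%) passed at an adjusted p under 0.05, 1738 higher and 1734 lower with loonamycin A. A change of at least 1 on the log2(FPKM + 1) scale was reached by 364 of the higher and 387 of the lower genes. Among 9459 protein-coding genes, 1291 were higher and 1547 lower. The 3 values of one group lay wholly above those of the other in 5097 genes (45.0%, where chance gives 10%). The count fell to 1802 without DMSO 2, to 1867 without loonamycin A 2 and to 1825 without loonamycin A 3, and the number higher by at least 1 grew from 364 to 577 without loonamycin A 1. Rescaling each library to one summed FPKM moved the median log2 fold change of all genes from 0.03 to -0.23 and gave 875 higher and 2875 lower genes, 23.3% higher in place of 50.1%, with 167 higher and 839 lower by at least 1.

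**Figure D1:**
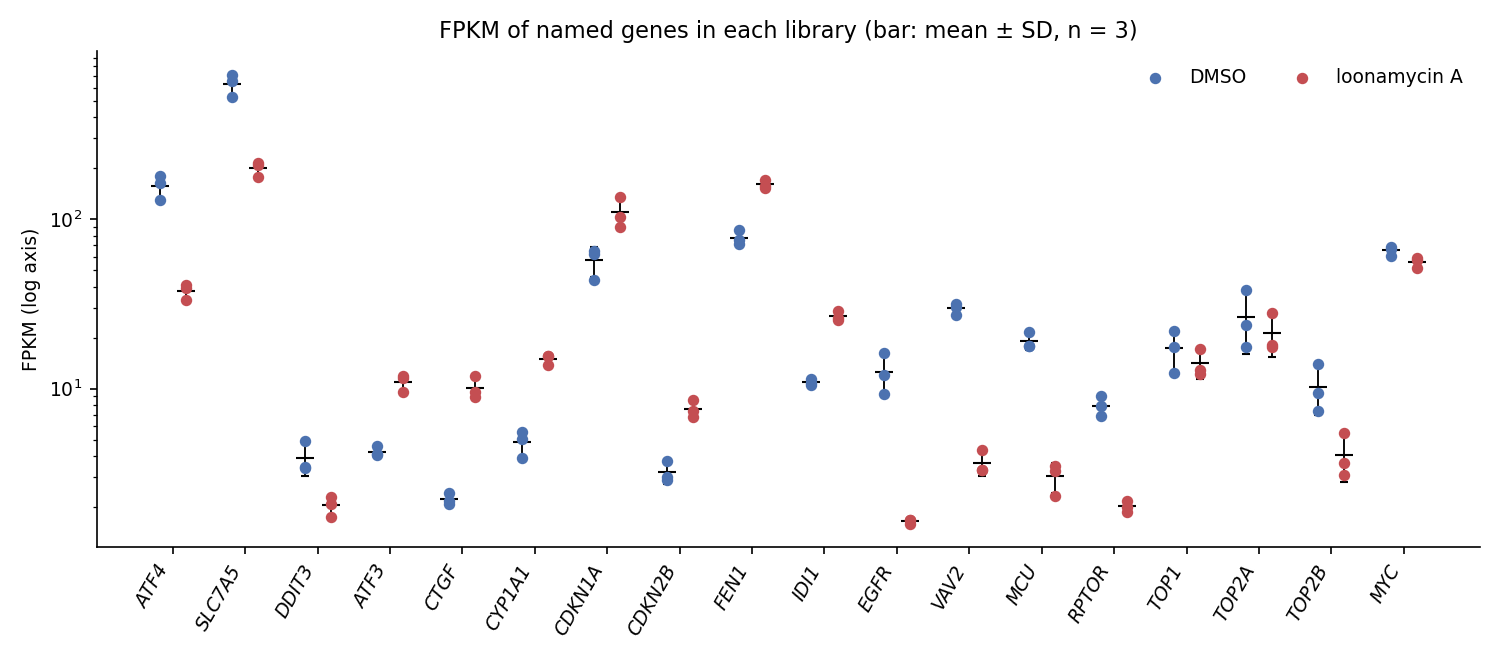
FPKM of 18 named genes (log axis) in each of the 3 DMSO and 3 loonamycin A libraries, with points for libraries and bars for mean ± SD. The ATF4 libraries fell from a mean of 158 to 37.8 and the CTGF libraries rose from 2.22 to 10.1, while TOP1, TOP2A and MYC did not pass the test.

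The 12 protein-coding genes with the largest decreases were taken from those that passed and whose 3 loonamycin A values lay below their 3 DMSO values. VAV2 (ENSG00000160293, chromosome 9, 133761894 to 133992604) fell by 2.73 on the log2 scale (SE 0.14, adjusted p = 0.00021). MCU, the pore of the mitochondrial calcium uniporter (chromosome 10, 72692131 to 72887694), and EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628) each fell by 2.32 (SE 0.16 and 0.18). The zinc finger gene ZNF469 changed by -2.36, the kinase CDK18 by -2.26, the transcription factor GTF2IRD1 by -2.21, and the spindle checkpoint gene MAD1L1 by -2.11. SH3RF3, FAF1, TBL1X, THRAP3 and the focal adhesion gene TNS3 changed by -2.14, -2.14, -2.11, -2.09 and -2.07. The median genomic span of these 12 genes was 213 kb, and 9 of them were longer than 100 kb.

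The 12 protein-coding genes with the largest increases had a median span of 2.44 kb, and 0 of them were longer than 100 kb. H2AFJ, a histone H2A variant, rose from 7.34 ± 1.72 to 35.7 ± 8.97 (log2 fold change 2.13, SE 0.23, adjusted p = 0.000587). MARCKSL1 (ENSG00000175130, chromosome 1, 32333832 to 32336379) rose by 1.91 (SE 0.16), and CTGF (ENSG00000118523, chromosome 6, 131948176 to 131951373) by 1.78 (SE 0.14, adjusted p = 0.000274). CYSRT1 rose by 1.95, SH2D5 by 1.79, the mannosyl transfer subunit DPM3 by 1.73, the cancer-testis gene CT83 by 1.72 and the Wnt receptor FZD9 by 1.71. MBLAC1 (1.88) and RBM12 (1.79) overlap AC073842.2 and CPNE1, and their values are uncertain because the strand setting of the counting is not stated. HLA-B, an antigen-presenting class I gene, had a log2 fold change of 2.20 (SE 0.67, adjusted p = 0.0375) from DMSO values of 0.375, 12 and 2.15. Its reads can be split with closely related HLA genes, and its adjusted p was 0.0581 without DMSO 1 (where the log2 fold change was 1.46), 0.101 without DMSO 3, 0.0958 without loonamycin A 2 and 0.093 without loonamycin A 3. CUTA had a log2 fold change of 1.75 (adjusted p = 0.031), with adjusted p of 0.0733, 0.0765, 0.0969 and 0.0814 without DMSO 2, DMSO 3, loonamycin A 2 and loonamycin A 3.

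Among 15 genes named in advance, 6 passed the test. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 57.1 ± 11.5 to 110 ± 23.6 (log2 fold change 0.93, SE 0.22, adjusted p = 0.0146, and 0.0559 without loonamycin A 2). ATF3, a stress-induced transcription factor, rose from 4.23 ± 0.28 to 11 ± 1.26 (1.19, adjusted p = 0.00068). TOP2B, a DNA topoisomerase II, fell from 10.3 ± 3.32 to 4.05 ± 1.24 (-1.14, adjusted p = 0.0093). GADD45A, a growth arrest gene, rose by 0.45 (adjusted p = 0.0255, and 0.130, 0.0843 and 0.112 without DMSO 2, loonamycin A 2 and loonamycin A 3), and the S-phase cyclin CCNE2 rose by 0.62 (adjusted p = 0.0209, and 0.0773 and 0.0776 without DMSO 2 and loonamycin A 2). DDIT3, a target of ATF4 in endoplasmic reticulum stress, fell by 0.68 (adjusted p = 0.0129, and 0.0589 without loonamycin A 3). The values that did not pass were -0.26 for TOP1, -0.34 for MDM2, -0.23 for MYC, -0.26 for CCNB1, -0.27 for MKI67, -0.15 for HMOX1 and -0.46 for FOXO1 (-0.60, adjusted p = 0.031, without loonamycin A 1). TOP2A also did not pass, at -0.27 with all libraries and 0.019 without DMSO 3, nor did CCND1, at 0.19 as deposited and -0.12 with the libraries rescaled to one sum. With 1 library left out, TOP1 ran from -0.46 (DMSO 1) to -0.078 (DMSO 3), MKI67 from -0.44 (DMSO 1) to -0.036 (DMSO 3), HMOX1 from -0.31 (DMSO 3) to -0.0098 (loonamycin A 1), TOP2A from -0.52 (DMSO 1) to 0.019 (DMSO 3) and CCND1 from 0.084 (loonamycin A 1) to 0.26 (loonamycin A 3), and none of these 5 passed in those fits. Other settings made some calls: MYC, CCNB1 and HMOX1 passed with the libraries rescaled to one sum (-0.55, -0.58 and -0.46), and MDM2, MYC, CCNB1, MKI67 and FOXO1 with a term for DMSO 3 and loonamycin A 1 (adjusted p = 0.0145, 0.0432, 0.015, 0.0398 and 0.00374). MYC and FOXO1 also passed with those 2 libraries left out (-0.32 and -0.46), MYC after quantile normalization (-0.44), and CCNB1 with the trend with GC content and exonic length removed (-0.29), while TOP1, TOP2A and CCND1 passed in none of the settings run. DDIT3, CCNE2, MDM2 and CCND1 overlap other tested genes, so their values are uncertain without a stated strand.

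Of 41 gene lists fixed in advance, 37 had at least 5 tested members, and camera found 2 lists lower and 3 higher than the other genes at an adjusted p under 0.05. Genes of the integrated stress response and ATF4 targets were lower, and so were PI3K/AKT/mTOR pathway genes. Cytosolic ribosomal proteins, nuclear oxidative phosphorylation subunits and mitochondrially encoded genes were higher. With an estimated correlation between genes in place of the preset 0.01, 0 lists passed in camera (smallest adjusted p = 0.559), 3 lists had an unadjusted p under 0.05, and limma's fry, which asks whether a list's genes move one way, called 19, among which were 3 of these 5. The lists that fry did not call were cytosolic ribosomal proteins (adjusted p = 0.169) and nuclear oxidative phosphorylation subunits (adjusted p = 0.163). Leaving out DMSO 1, loonamycin A 2 or loonamycin A 3 gave 8, 8 and 10 lists, and these 5 passed in each fit that left out a library. Quantile normalization ended the call of the 3 higher lists.

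In the list of integrated stress response and ATF4 targets, 19 of 32 tested genes fell and 3 rose, with the same 19 and 3 adjusted over the list alone. The median log2 fold change was -0.64 (camera adjusted p = 7.71e-05, and adjusted p = 0.559 with an estimated correlation). ATF4 itself (ENSG00000128272, chromosome 22, 39519695 to 39522685) fell by 2.03 (SE 0.18, adjusted p = 0.000306). SLC7A5, the large neutral amino acid transporter (chromosome 16, 87830023 to 87869488), which overlaps MIR6775, fell from 632 ± 96.4 to 201 ± 19.9 (-1.64, SE 0.19). The 3 members that rose were ATF3 (1.19), the related transcription factor ATF5 (1.48, SE 0.20, overlapping NUP62) and PPP1R15A (0.59), a phosphatase subunit that reverses eIF2 alpha phosphorylation. ATF5 and PPP1R15A were named after their values were seen. The adjusted p of PPP1R15A, 0.0329, became 0.109, 0.074, 0.123 and 0.0994 without DMSO 2, DMSO 3, loonamycin A 2 and loonamycin A 3.

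Of 16 PI3K/AKT/mTOR pathway genes, 5 fell over all genes and 6 adjusted over the list alone, and 0 rose. The median was -0.41 (camera adjusted p = 0.00161, and adjusted p = 0.559 with an estimated correlation), and -0.22 after the trend of other genes with span, exonic length and GC content was removed. RPTOR, the scaffold of mTOR complex 1 (chromosome 17, 80544819 to 80966371), fell from 7.94 ± 1.09 to 2.02 ± 0.144 (-1.56, SE 0.13), and the kinase subunit PIK3CB fell from 2.84 ± 0.946 to 0.739 ± 0.229 (-1.12). The other 3, named after their values were seen, were the mTOR inhibitor DDIT4 (-0.81), MTOR itself (-0.77) and the mTOR-restraining tumour suppressor TSC2 (-0.55, overlapping NTHL1 and PKD1). The adjusted p of DDIT4 was 0.0514 without DMSO 2, that of MTOR 0.0502 without loonamycin A 3, and that of TSC2 0.0595, 0.0946, 0.0548 and 0.0678 without DMSO 1, DMSO 2, loonamycin A 2 and loonamycin A 3.

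Cytosolic ribosomal protein genes had a median of 0.52 over 49 tested members (camera adjusted p = 7.71e-05, and adjusted p = 0.692 with an estimated correlation), and of 0.17 after the trend with span, exonic length and GC content was removed. Single genes of this list were less certain: 5 rose over all genes and 0 adjusted over the list alone, with 20 higher and 0 lower at an unadjusted p under 0.05. The 5 were RPS27 (0.94, SE 0.26), RPS24 (0.73), RPL38 (0.65), RPS12 (0.73) and RPL37 (0.71), of which RPL38, RPS12 and RPL37 were named after their values were seen. Without loonamycin A 2 their adjusted p were 0.113, 0.116, 0.150, 0.153 and 0.172, without loonamycin A 3 they were 0.116, 0.122, 0.156, 0.175 and 0.184, without DMSO 2 they were 0.0822, 0.125, 0.116, 0.158 and 0.131, and without DMSO 3 they were 0.0789, 0.0649, 0.0951, 0.108 and 0.118. Without DMSO 1, RPL38 and RPL37 had adjusted p of 0.0519 and 0.0566. Many of these genes have pseudogene copies that can share reads, and RPS12 and RPL37 overlap small nucleolar RNA genes. Libraries DMSO 3 and loonamycin A 1 stood apart from the other 4 on the second principal component, and the list's median difference was 0.36 within that pair and 0.60 within the other 4, with up to 0.74 between libraries of one group.

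Nuclear oxidative phosphorylation subunits had a median of 0.45, with 11 of 35 members higher and 0 lower, and the same 11 and 0 adjusted over the list alone (camera adjusted p = 0.00217, and adjusted p = 0.692 with an estimated correlation). The median was 0.25 without DMSO 3, 0.30 without loonamycin A 2 and 0.157 after the trend with span, exonic length and GC content was removed. It too moved with the libraries that stood apart: the difference was 0.36 between DMSO 3 and loonamycin A 1 and 0.47 within the other 4, with up to 0.65 between libraries of one group, and loonamycin A 1 lay below DMSO 1 by 0.13 on this list and by 0.17 on the ribosomal list. UQCRFS1, the Rieske iron-sulfur protein of complex III, rose from 29.9 ± 2.84 to 44.7 ± 3.93 (0.57, SE 0.15), and the complex I subunit NDUFB8, which overlaps HIF1AN, from 6.75 ± 1.31 to 10.4 ± 1.43 (0.56). UQCRFS1 had adjusted p of 0.0806, 0.0648 and 0.117 without DMSO 2, loonamycin A 2 and loonamycin A 3, and NDUFB8 of 0.126, 0.0747, 0.119 and 0.0948 without DMSO 2, DMSO 3, loonamycin A 2 and loonamycin A 3. Of 15 mitochondrially encoded genes, 4 rose over all genes and 1 adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.000583, and adjusted p = 0.655 with an estimated correlation). This median was -0.021 after quantile normalization, and with the trend with GC content and exonic length removed it was 0.19 and no longer passed (camera adjusted p = 0.181, and 0.174 with a replicate block as well). The 10 highest genes of the libraries were all mitochondrially encoded, and quantile normalization gives the highest ranks of each library the same values. It can thus remove a shift that these genes share, so the -0.021 does not show whether they rose. The ribosomal RNA MT-RNR1 rose from 969 ± 70.3 to 1772 ± 266 (0.86), and MT-RNR2 from 4032 ± 234 to 6735 ± 589 (0.74, and -0.041 after quantile normalization). MT-ATP8 (0.64, overlapping MT-ATP6) and MT-ND3 (0.88), named after their values were seen, were the other members that rose. Without loonamycin A 2 the adjusted p of MT-RNR1, MT-RNR2, MT-ATP8 and MT-ND3 were 0.0746, 0.148, 0.128 and 0.188, and without loonamycin A 3 they were 0.0928, 0.146, 0.156 and 0.157. MT-RNR2, MT-ATP8 and MT-ND3 had 0.0691, 0.115 and 0.0628 without DMSO 1 and 0.0840, 0.0825 and 0.155 without DMSO 3, and MT-RNR1, MT-RNR2 and MT-ND3 had 0.0541, 0.132 and 0.0956 without DMSO 2.

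**Figure D2:**
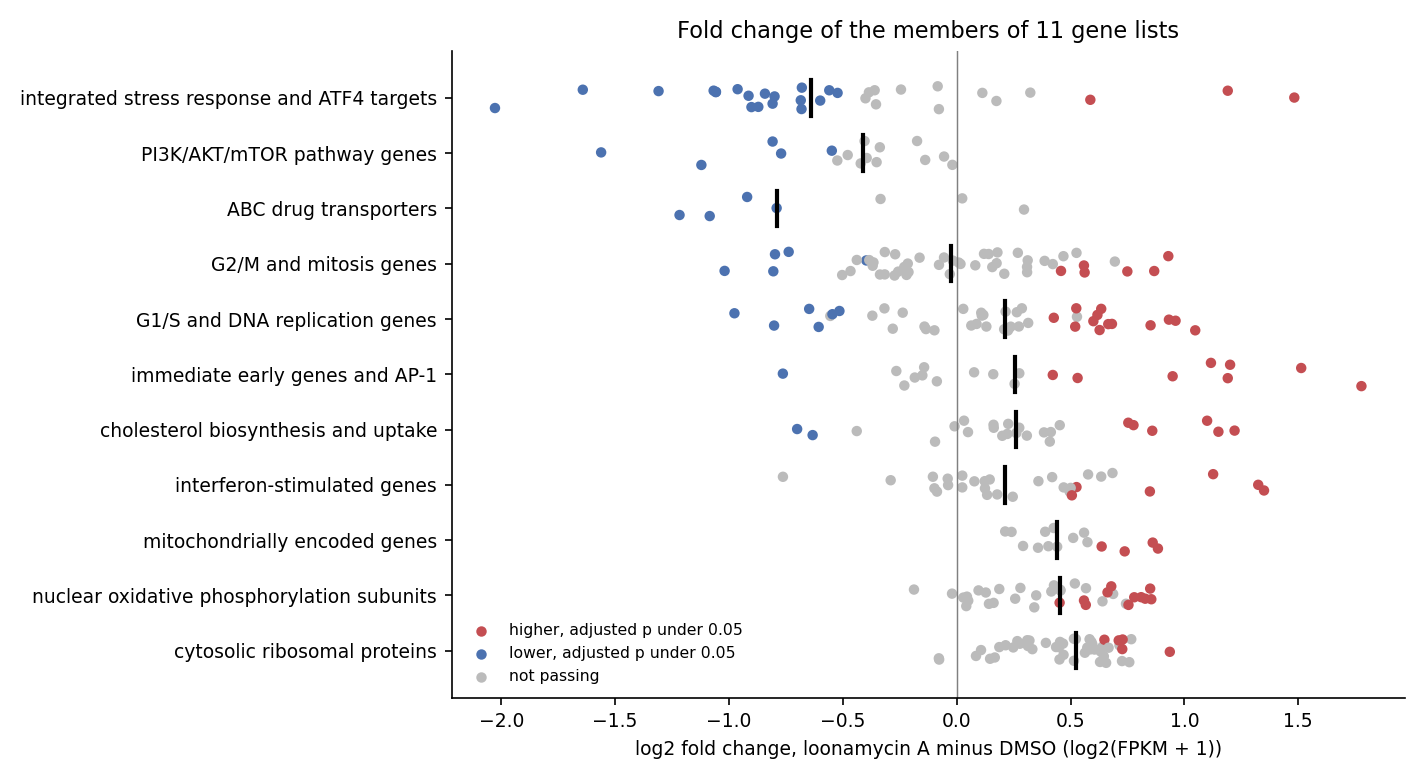
Log2 fold change (loonamycin A minus DMSO) of each tested member of 11 gene lists, with 1 point per gene coloured by its limma call and a bar at the list's median. The medians run from -0.79 for ABC drug transporters and -0.64 for ATF4 targets to 0.52 for cytosolic ribosomal proteins.

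Another 4 lists had a camera adjusted p of 0.0564 and did not pass, although single members changed. Of 19 immediate early and AP-1 genes, 8 rose and 1 fell, also adjusted over the list alone (median 0.25, and 0.16 without loonamycin A 1), and CTGF and IER5 (1.51) rose most clearly. Of 25 cholesterol biosynthesis and uptake genes, 6 rose and 2 fell, also adjusted over the list alone (median 0.26), and IDI1 rose from 10.9 ± 0.49 to 26.8 ± 1.59 (1.22) and MSMO1 from 11.5 ± 0.929 to 25.8 ± 1.8 (1.10). Of 30 interferon-stimulated genes, 6 rose over all genes and 5 adjusted over the list alone (median 0.21), with IFIT1, which overlaps LIPA, at 1.13 and SAMD9 at 0.85. The adjusted p of SAMD9 was 0.0537 without DMSO 2. Of 7 ABC drug transporters, 4 fell, also adjusted over the list alone (median -0.79), with the multidrug resistance proteins ABCC1 (-1.08) and ABCC3 (-0.79) among them. With the libraries rescaled to one sum, where the median of all genes was -0.23, the medians of the immediate early, cholesterol and interferon lists were -0.01, -0.05 and -0.03. After the trend with span, exonic length and GC content was removed, the medians of the immediate early, interferon and ABC transporter lists were 0.02, 0.12 and -0.21.

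Single cell cycle genes moved in both directions, where 30.7% of all tested genes passed. Neither the G1/S nor the G2/M list passed in camera (adjusted p = 0.265 and 0.930). Of 44 G1/S and DNA replication genes, 13 rose and 6 fell (13 and 7 adjusted over the list alone). The flap endonuclease FEN1, which overlaps TMEM258 and FADS2, rose from 77.5 ± 7.59 to 161 ± 9.48 (1.05), and the cohesion factor DSCC1 rose by 0.93. Of 50 G2/M and mitosis genes, 6 rose and 5 fell over all genes, and 1 rose and 0 fell adjusted over the list alone, with 11 higher and 9 lower at an unadjusted p under 0.05. The mitotic kinase CDK1 rose from 16.5 ± 2.11 to 32.6 ± 5.49 (0.93), and its inhibitory kinase PKMYT1, which overlaps PAQR4 and KREMEN2, rose by 0.87 (adjusted p = 0.0165, and 0.0643 and 0.0587 without loonamycin A 2 and loonamycin A 3). Of 8 cyclin-dependent kinase inhibitors, 4 rose and 1 fell, also adjusted over the list alone, with CDKN2B from 3.20 ± 0.456 to 7.60 ± 0.9 (1.04) and CDKN2D from 2.86 ± 0.688 to 8.26 ± 1.69 (1.26). Of 16 replication-dependent histones, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with HIST1H3B at 1.2 and HIST2H2BE at 0.83. HIST2H2BE no longer passed with the libraries rescaled to one sum (adjusted p = 0.0758). HIST1H3B no longer passed with trends with GC content and exonic length removed together with a replicate block (adjusted p = 0.0567). Histone genes share near-identical sequence, so their reads can be split between copies.

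Of 33 DNA damage signalling and repair genes, 1 rose and 4 fell over all genes (1 and 2 adjusted over the list alone). The checkpoint kinase CHEK2, which overlaps HSCB, fell from 4.89 ± 0.535 to 2.25 ± 0.507 (-0.86), and the Fanconi anaemia gene FANCB rose by 0.79 (adjusted p = 0.0146, and 0.0562 and 0.0531 without DMSO 2 and loonamycin A 2). Of 5 topoisomerases, 1 fell and 0 rose, also adjusted over the list alone: TOP2B passed, and the mitochondrial TOP1MT stood at -0.29 (it passed at -0.57 with the libraries rescaled to one sum, at -0.38 with DMSO 3 and loonamycin A 1 left out, and with a term for them). Of 30 apoptosis and BCL2 family genes, 4 rose and 1 fell, also adjusted over the list alone, with the death activator BCL2L11, which overlaps MIR4435-2HG, from 2.61 ± 0.335 to 6.16 ± 1.11 (0.98) and cytochrome c, CYCS, at 0.80. Of 13 senescence-associated secretory genes, 4 rose and 2 fell, also adjusted over the list alone. The chromatin protein HMGB2, a nuclear and not a secretory member of that list, rose by 0.73, and no longer passed with the libraries rescaled to one sum (adjusted p = 0.0563). It is counted among the 4 that rose, so that count is not one of secreted factors alone.

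Of 25 genes of the unfolded protein response, 1 rose and 4 fell, also adjusted over the list alone, with the transcription factor CREB3L2 at -0.93 and HERPUD1, a factor of protein degradation in the endoplasmic reticulum, at -0.56. The median of that list was 0.02 and its mean -0.05. Of 20 heat shock proteins, 3 rose and 1 fell (2 and 1 adjusted over the list alone). The co-chaperone DNAJB6 fell by 1.07 and DNAJB4 rose by 0.63 (adjusted p = 0.0126, and 0.0655, 0.0547 and 0.0518 without DMSO 2, loonamycin A 2 and loonamycin A 3). Of 30 NRF2 targets and antioxidant genes, 4 rose and 9 fell (5 and 9 adjusted over the list alone), with ABCC1 and malic enzyme ME1 (-1.10) lower. Of 35 autophagy and lysosome genes, 6 rose and 3 fell (5 and 3 adjusted over the list alone). ATG7, an enzyme of autophagosome formation that overlaps VGLL4, fell from 4.65 ± 0.531 to 1.64 ± 0.0952 (-1.10), and the lysosomal enzyme GLA rose by 0.63 (adjusted p = 0.0126, and 0.0541 and 0.0728 without DMSO 2 and loonamycin A 3). Of 22 hypoxia targets, 2 rose and 6 fell, also adjusted over the list alone, with the demethylase KDM4B at -1.17 and the peptide hormone ADM at 1.05.

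Of 21 glycolysis genes, 1 rose and 3 fell, also adjusted over the list alone. Aldolase C, ALDOC, rose from 30.8 ± 6.22 to 60.6 ± 8.19 (0.97) and phosphofructokinase PFKP fell by 0.69 (adjusted p = 0.0206, and 0.0566, 0.0923, 0.0616 and 0.0595 without DMSO 1, DMSO 2, loonamycin A 2 and loonamycin A 3). Of 19 fatty acid synthesis genes, 1 rose and 4 fell (1 and 3 adjusted over the list alone), with ME1 at -1.10 and the desaturase FADS2, which overlaps FEN1, at -0.76. Of 32 ribosome biogenesis and MYC target genes, 2 rose and 2 fell over all genes, 0 passed adjusted over the list alone, and 3 were higher and 2 lower at an unadjusted p under 0.05. RRS1 rose by 0.65 (adjusted p = 0.0151, and 0.0649, 0.0624 and 0.0693 without DMSO 2, loonamycin A 2 and loonamycin A 3) and NOP56 by 0.44 (adjusted p = 0.0333, and 0.0618, 0.145, 0.1 and 0.134 without DMSO 1, DMSO 2, loonamycin A 2 and loonamycin A 3).

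Among signalling lists, 4 of 20 YAP/TAZ target genes rose and 7 fell, also adjusted over the list alone, with CTGF at 1.78 and CYR61, a related secreted matrix protein, from 18.9 ± 1.94 to 44.7 ± 2.07 (1.2). Of 21 TGF-beta targets, 5 rose and 6 fell (7 and 8 adjusted over the list alone), and the repressor of E-cadherin SNAI1 rose from 2.30 ± 0.293 to 7.69 ± 1.61 (1.39). Of 11 ERK pathway feedback genes, 3 rose and 1 fell, also adjusted over the list alone, with the phosphatase DUSP2 at 1.38 and the AP-1 subunit FOSL1 at 0.95. Of 20 FOXO target genes, 4 rose and 2 fell, also adjusted over the list alone. The receptor IGF1R fell by 0.91 and TXNIP, an inhibitor of glucose uptake, rose by 1.19. Of 17 NF-kB targets, chemokines and cytokines, 4 rose and 1 fell, also adjusted over the list alone, with the adhesion molecule ICAM1 at 0.65 and the adaptor TRAF1 at 0.62. Of 9 aryl hydrocarbon receptor targets, 1 rose and 2 fell, also adjusted over the list alone: CYP1A1, a cytochrome P450 (chromosome 15, 74719542 to 74725610), rose from 4.82 ± 0.864 to 15.0 ± 1.05 (1.46, SE 0.15), while SLC7A5 fell. Of 4 protein kinase C isoforms tested, 2 fell over all genes and 3 adjusted over the list alone, with PRKCA from 2.47 ± 0.606 to 0.193 ± 0.0174 (-1.53) and PRKCZ, which overlaps FAAP20 and PRKCZ-AS1, at -0.87. The loonamycin A mean of PRKCA lay below the pseudocount of 1, and its log2 fold change ran from -3.65 to -0.52 over the alternative settings. The 4 isoforms had a median span of 109 kb, and 40.7% of all protein-coding genes from 64.7 kb fell. The span trend was not removed for this list, so its decreases are not set apart from that trend.

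Of 6 genes of antigen presentation by MHC class I, 2 rose and 1 fell over all genes (3 and 1 adjusted over the list alone), with the class I regulator NLRC5 from 9.26 ± 0.842 to 5.07 ± 0.488 (-0.76). The other of the 2 smallest p in that list belonged to HLA-B, whose call was lost in 4 of the fits that left out a library (highest adjusted p = 0.101, without DMSO 3; 0.0581, 0.0958 and 0.093 without DMSO 1, loonamycin A 2 and loonamycin A 3). Of 25 mesenchymal and migration genes, 2 rose and 3 fell (2 and 2 adjusted over the list alone), with SNAI1 higher and N-cadherin, CDH2, at -0.78, and a list median above 0 (0.00424) with a mean below it (-0.00528). Of 15 breast cancer stemness genes, 1 rose and 1 fell, also adjusted over the list alone: the adhesion molecule EPCAM rose by 0.59 and the receptor NOTCH3 fell from 14.9 ± 2.2 to 5.45 ± 0.722 (-1.30). EPCAM no longer passed with the libraries rescaled to one sum. Of 8 basal epithelial markers, 1 rose and 2 fell, also adjusted over the list alone, with EGFR lower and SFN, the 14-3-3 sigma protein, from 222 ± 53.1 to 587 ± 141 (1.40). Of 12 luminal markers, 3 rose and 1 fell, also adjusted over the list alone, with EPCAM higher and the transcription factor XBP1 at -0.62 (adjusted p = 0.0161, and 0.0804, 0.0553 and 0.0684 without DMSO 2, loonamycin A 2 and loonamycin A 3).

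Markers of retina and immune cells were low, while some fibroblast and endothelial markers were expressed. Of the photoreceptor and retina markers, ROM1, which overlaps EML3, alone was tested, at 1.71 ± 0.897 and 3.15 ± 0.165 FPKM (0.67, adjusted p = 0.0522; 0.91, adjusted p = 0.00994, without DMSO 1 and 0.42, adjusted p = 0.0966, without DMSO 3), and the highest mean over all 6 libraries of any member of that list was 2.43. It passed adjusted over the list alone, a list of 1 tested gene. The immune cell markers had 0 tested members and a highest mean FPKM over the 6 libraries of 0.772. Of 4 fibroblast and endothelial markers, 1 rose over all genes and 2 adjusted over the list alone. ESAM, an endothelial adhesion molecule that overlaps AP000866.2, rose from 11.6 ± 2.75 to 22.3 ± 1.61 (0.91), and the matrix proteoglycan LUM stood at 65.2 ± 6.15 and 99.4 ± 22.1 (0.58, adjusted p = 0.0548, and 0.0123 without loonamycin A 1).

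Genes with long genomic spans were lower and short genes higher with loonamycin A, in a comparison set in advance because indolocarbazoles include topoisomerase I poisons. Over 9459 protein-coding genes in 4 equal bins of span, the median log2 fold changes were 0.37, 0.12, -0.08 and -0.40 from the shortest to the longest bin. In the shortest bin (up to 12.1 kb) 29.7% of genes rose and 3.21% fell, and in the longest (from 64.7 kb) 2.83% rose and 40.7% fell. With 10 bins, 543 of 946 genes fell in the longest (57.4%). The longest of the 4 bins lay below the shortest (difference -0.77, exact two-sided permutation p = 0.10, the smallest that 3 against 3 libraries allow). Per library, relative to the mean of the 3 DMSO libraries, this difference was -0.30, -0.09 and 0.40 for DMSO 1 to 3. It was -0.44, -1.04 and -0.87 for loonamycin A 1 to 3. It was -0.82 between DMSO 3 and loonamycin A 1 and -0.75 between the groups of the other 4 libraries. Libraries of one group also differed, by 0.70 for DMSO 3 minus DMSO 1 and by -0.61 for loonamycin A 2 minus loonamycin A 1. For loonamycin A 1 minus DMSO 1 the difference was -0.13. The mitochondrially encoded genes, listed in advance as a sign of RNA quality, also moved with treatment (median 0.44, camera adjusted p = 0.000583, and adjusted p = 0.655 with an estimated correlation). Their median was -0.021 after quantile normalization, which can remove a shift shared by the highest genes. Spearman's rho across genes, which are not independent replicates, was -0.59 between span and fold change and -0.43 for exonic length.

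**Figure D3:**
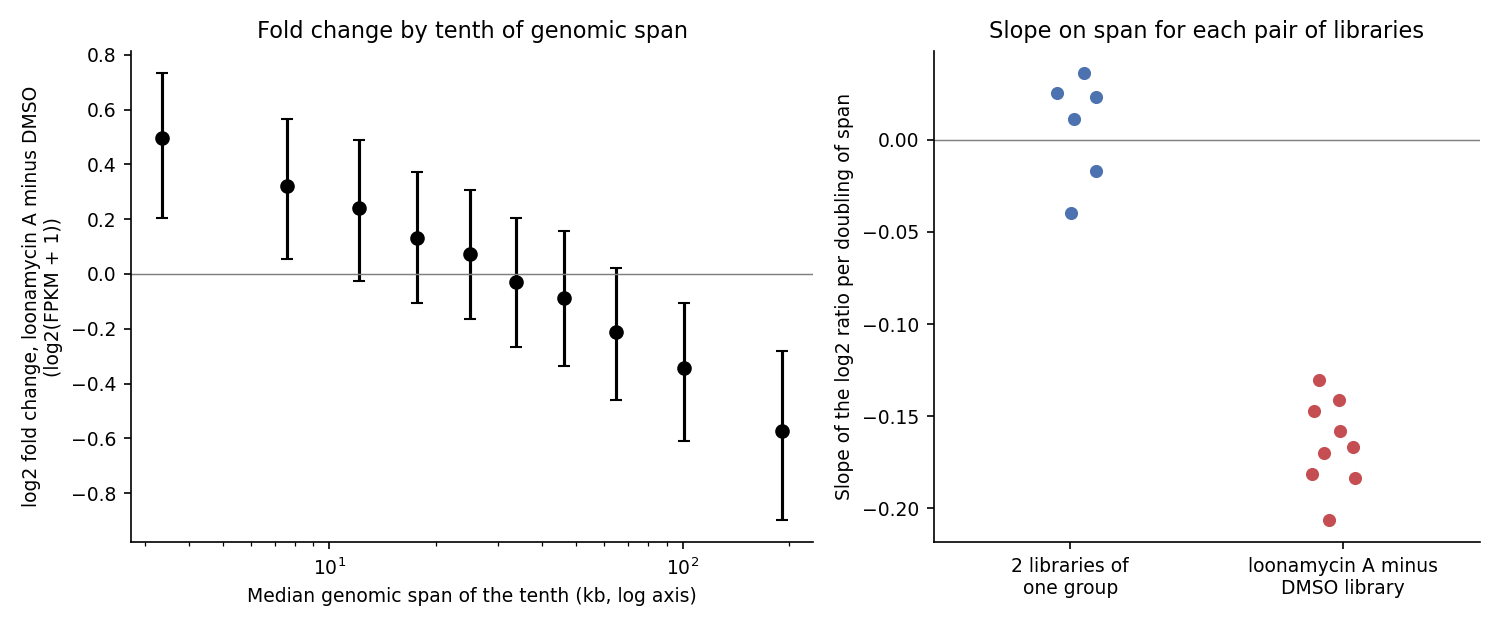
Left, the median log2 fold change (points) with its quartiles (bars) in 10 bins of protein-coding genes by genomic span (kb, log axis), running from 0.50 in the shortest to -0.57 in the longest bin. Right, the slope of the log2 ratio per doubling of span, with exonic length and GC content held fixed, for the 6 pairs of libraries of one group and the 9 pairs of a loonamycin A and a DMSO library.

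The composition of the libraries was compared as shares of summed FPKM. Mitochondrially encoded genes took 21.7% ± 2.5 with DMSO and 24.5% ± 1.83 with loonamycin A (SD, n = 3, exact permutation p = 0.2). Cytosolic ribosomal protein genes took 5.03% ± 0.572 and 5.90% ± 0.831 (exact permutation p = 0.3). The 10 highest genes, led by MT-CO2, MT-CO1 and MT-CO3, were all mitochondrially encoded and so part of the first class. They took 17.5% ± 1.94 and 19.7% ± 1.22 (exact permutation p = 0.2). After adjustment over these 3 shares each exact p was 0.3, and none of the differences was shown to exceed the spread between replicates. The mitochondrial difference of 2.79 percentage points was 1.36 without DMSO 1, 1.75 without loonamycin A 1 and 1.499 with FPKM times gene length. With the 10 highest genes left out it was 0.93, which covers only the other mitochondrially encoded genes, since those 10 belong to the class. That of the 10 highest genes, 2.15, was 1.04 without DMSO 1, 1.39 with protein-coding genes only and 1.11 with FPKM times gene length, and the ribosomal one, 0.87, was 1.35 without loonamycin A 1, 0.58 without DMSO 3 and 1.62 with FPKM times gene length.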

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

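The alternatives with voom, with trends in GC content and exonic length removed, with DMSO 3 and loonamycin A 1 left out or given a term, and with chromosomes only were chosen after the data were seen. The count of 3472 genes was 1759 with a filter at a mean FPKM of 5, where 6060 genes were tested, 2129 with a replicate block, 1373 when limma's treat asked for more than a 1.2-fold change, 5885 without DMSO 3 and loonamycin A 1, and 6783 with a term for them. With 1 library left out it ran from 1802 (without DMSO 2) to 4417 (without loonamycin A 1), and was 1867 and 1825 without loonamycin A 2 and loonamycin A 3. Other settings gave from 2845 (no filter) to 4621 (trends removed), with 3552 from voom, which shared 3322 genes with the 3472. The 364 and 387 genes that moved by at least 1 became 631 and 736 with a pseudocount of 0.1, and 80 and 72 with a pseudocount of 5. The 5 gene lists became 11 without a filter, 2 after quantile normalization, 9 with protein-coding genes only, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 19 with fry, and ran from 5 (DMSO 3) to 10 (loonamycin A 3) with 1 library left out, with 8 without DMSO 1 and 8 without loonamycin A 2. The replicate numbers did not pair the libraries, with residual correlations of -0.61, 0.28 and -0.37, so the block removed degrees of freedom without a shared effect to account for. The lower fold change of long genes kept its direction in each setting run, from -0.33 (no filter) to -1.07 (10 bins), and with 1 library left out from -0.58 (DMSO 3) to -0.96 (loonamycin A 1), as did the 3 shares, whose differences ran with 1 library left out from 1.36 to 3.68 percentage points (mitochondrial), 0.58 to 1.35 (ribosomal) and 1.04 to 2.83 (10 highest genes). The named genes gave 2782 comparisons, of which 2525 kept their direction and side of the threshold, 223 no longer passed, 31 newly passed and 3 changed direction: CCND1 at -0.12 with the libraries rescaled to one sum, MT-RNR2 at -0.041 after quantile normalization, and TOP2A at 0.019 without DMSO 3 (from -0.52 to 0.019 with 1 library left out). CCND1 and TOP2A did not pass in the reported fit. Of 105 named genes that passed, 75 passed in each fit with 1 library left out, and rescaling to one sum ended 21 calls, each of a higher gene. Most named genes were picked for large changes or small p in these same libraries, so these counts do not stand for all 3472 genes. Without DMSO 2, for example, 81 of the 105 still passed, against 1786 of the 3472. The 10 lists followed, those with an adjusted p under 0.1, a choice made after the values were seen, gave 209 comparisons, with 165 unchanged in direction and threshold, 11 no longer passing, 32 newly passing and 1 changed in direction, the mitochondrially encoded genes at -0.021 after quantile normalization. Over the 37 tested lists, 39 of 775 comparisons changed direction, 38 of them in the 27 lists not followed, and 0 of those 38 passed in camera. The median-of-ratios scaling moved nothing beyond a factor common to all libraries, so it says nothing about stability. Quantile normalization can remove a shift shared by the highest genes, which were mitochondrially encoded, so the changes of direction of such genes under it decide nothing. The cause of the other changes was not tested. With 3 libraries per group, the exact tests cannot give a p under 0.1.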

Other observations

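The tests of the explanations below were written down before the values that they measure were seen, but on patterns found in these data, except for the test of a library state among 4 libraries and the comparison with a list's own spread between libraries, which were chosen only after the result was seen. The descriptions of protein families, biotypes and genes against the span trend were chosen only after the result was seen, as were the alternatives with DMSO 3 and loonamycin A 1 left out.

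Genes with long spans had lower fold changes, and a candidate technical source was a difference between libraries in exonic length or GC bias. With both held fixed over 9440 genes, the slope per doubling of span ran from -0.13 to -0.21 between each loonamycin A and each DMSO library, and was at most 0.0399 in size between libraries of one group. The weakest treated slope was thus 3.27 times the largest within a group, which argues against such a bias as the whole cause. The slope was negative in 9 of 9 treated pairs, and within each of 5 bins of exonic length the longest spans lay lower, by -0.58 to -0.70. That loonamycin A lowers transcripts of long genes is thus a hypothesis that stays open beside a difference in RNA quality, which was not measured. The mitochondrially encoded genes, its listed sign, were also higher with loonamycin A (median 0.44), and differed by up to 0.32 between libraries of one group. Their median of -0.021 after quantile normalization decides nothing, since that scaling can remove a shift shared by the highest genes.

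The ATF4 target list was lower with a median of -0.64, and the trend with span, exonic length and GC content predicted 0.07 for its genes. After the trend with span, exonic length and GC content was removed, its median was -0.65, outside the -0.14 to 0.16 of random lists of that size and beyond its largest difference between libraries of one group (0.075), which argues against the trend as the cause. Whether a lower ATF4 transcript level underlies the lower targets stays open: the median without ATF4 was -0.63, but leaving out 1 of 32 members cannot move it, so this value decides nothing. ATF4 protein was not measured, and ATF3, ATF5 and PPP1R15A rose.

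Cytosolic ribosomal protein and nuclear oxidative phosphorylation genes are short, and the trend predicted 0.36 and 0.28 of their medians of 0.52 and 0.45. Whether the trend is the whole cause stays open for both: its removal left 0.17 and 0.157, past the bounds of 0.13 and 0.156 from random lists that were written in advance, but such lists leave out the correlation within a list, and the lists still differed by up to 0.59 and 0.33 between libraries of one group. For the ribosomal genes, what was left was 0.02 between DMSO 3 and loonamycin A 1, and 0.16 to 0.30 among the other 4 libraries, where libraries of one group differed by up to 0.14, so the pair did not bear out the remainder seen in the other 4. Among the other 4 libraries the weakest difference between a treated and a DMSO library (0.46) was 2.45 times the largest between libraries of one group (0.19). A state of DMSO 3 and loonamycin A 1 alone would leave no such difference there, which argues against it as the whole cause for the ribosomal genes. This comparison was chosen after the result was seen, and its 0.19 is small partly because the libraries that stood apart were set aside. The bound written in advance pointed the other way, at 0.485 times the largest difference between all libraries of one group (0.74), but that yardstick contains the state itself, which is balanced over the groups; reads shared with pseudogenes were not tested.

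The 10 splits of the 6 libraries are too few for a share under 0.05. Each split other than the real one also mixes loonamycin A and DMSO libraries in both of its groups. A treatment difference then enters the spread within groups and lowers the number of genes called. The counts of the other splits are therefore not what libraries without a treatment difference would give. For genes, the real split gave 3472 and the highest other 0 (limma; 2276 at an unadjusted p under 0.05 for DMSO 1 with loonamycin A 2 and 3), and 1 of the 10 splits reached the real count. For lists, the real split gave 5 and the highest other 9 (DMSO 1 with loonamycin A 1 and 2), and 7 of the 10 reached the real count.

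Some genes moved against the span trend. Of 1435 protein-coding genes of at least 100 kb, 24 rose and 727 fell, and among those that rose were SCOC (0.92), the vitamin D receptor VDR (0.84) and TUBGCP3 (0.72). Of 1941 genes under 10 kb, 596 rose and 63 fell, and ATF4 (-2.03), the splicing factor SRSF1 (-1.34, overlapping AC015813.5), TMEM250 (-1.27) and NUDT18 (-1.23) fell most. After the trend with span, exonic length and GC content was removed, the median of the cholesterol list was 0.24, above the 0.19 of random lists. That of the PI3K/AKT/mTOR list, for which the trend predicted -0.26, was -0.22, below the -0.20 of random lists. The largest differences of these 2 lists between libraries of one group were then 0.086 and 0.058. The immediate early, interferon and ABC transporter lists, at 0.02, 0.12 and -0.21, lay within random lists (up to 0.20 and 0.17, and down to -0.32).

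Among 110 families named in the deposited table with enough tested members, 25 passed in camera at the preset correlation, 22 lower and 3 higher, and none with an estimated correlation (smallest adjusted p = 0.328). RhoGEF genes had 1 of 31 members higher and 14 lower (median -0.41, adjusted p = 0.000579), protein kinases 12 of 206 higher and 57 lower (median -0.22), and myosin heads 0 of 11 higher and 6 lower (median -0.49). After the trend with span, exonic length and GC content was removed these medians were -0.16, -0.05 and -0.18. KH domain RNA-binding genes had 0 of 24 higher and 11 lower (median -0.42, and -0.25 after the trend was removed). The 3 higher families were C2H2 zinc fingers, with 14 of 59 higher and 2 lower (median 0.23, and 0.10 after the trend was removed), histones, with 11 of 28 higher and 2 lower (median 0.45, and -0.26 after the trend was removed), and MHC class I, with 3 of 22 higher and 0 lower (median 0.57, and 0.32 after the trend was removed), of which 17 lie on alternative contigs and can share reads. Antisense RNAs had 111 of 341 higher and 39 lower, but 250 of the 341 overlap other tested genes, so without a stated strand these counts are uncertain; the other members gave 38 higher and 9 lower. Long intergenic RNAs had 100 of 311 higher and 36 lower, and 83 and 31 among those that overlap no tested gene. Antisense and long intergenic RNAs are short, with median spans of 3.08 and 3.40 kb, and the span trend was not removed for them. Protein-coding genes of up to 12.1 kb had a median log2 fold change of 0.37, which neither class exceeded. With the libraries rescaled to one sum the medians were 0.03 for C2H2 zinc fingers, 0.03 for antisense RNAs (0.23 as deposited) and -0.002 for long intergenic RNAs (0.22 as deposited), against -0.23 for all genes. Mitochondrial transfer RNAs, with a median span of only 0.069 kb, had 12 of 21 higher and 0 lower. Their median was 0.89 as deposited and 0.56 with the libraries rescaled to one sum. Mitochondrially encoded genes were also the listed sign of RNA quality.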
